A study of Schizosaccharomyces pombe
Saccharomyces cerevisiae with 16 samples.

How the data were processed

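RNA was measured in Saccharomyces cerevisiae (budding yeast) strains in which a subunit of Mediator could be degraded on demand. Mediator is the coactivator complex that links gene-specific activators to RNA polymerase II, and Med14 and Med17 are subunits of its architecture. Each strain carried the rice F-box protein OsTIR1 and an auxin-inducible IAA7 degron on Med14 or on Med17, so that auxin brings the tagged protein to the proteasome. Per the labels, cultures received 500 µM auxin or the solvent DMSO for 30 min and then 5 mM 4-thiouracil (4tU), a uracil analogue that is built into new RNA, for 6 min. Cells of the fission yeast S. pombe were mixed in before RNA extraction. Libraries were made from total RNA and from the purified 4tU-labelled fraction, called newly synthesized RNA here, with a stranded total RNA kit and ribosomal RNA removal. The 2 strains, 2 treatments and 2 kinds of RNA gave 8 groups of 2 biological replicates, 16 libraries in all. The groups came from the source and treatment labels. The genotype field of the Med17 samples names a Med14 tag, while their strain and source fields name Med17, and the latter were used.

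Reads were demultiplexed with bcl2fastq 2.17.1.14 and the genome build was sacCer3, per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here. Reads of overlapping or antisense transcripts therefore could not be separated from those of a gene. The deposited tables hold raw read counts per S. cerevisiae gene for each library, per the file headers, with 6859 genes for newly synthesized RNA and 6805 for total RNA. Every column was mapped to a sample by its title. The authors also deposited normalized counts, a signal equal to the raw count times a single constant per library. No S. pombe genes are among the genes used here, and the origin of the constants is not given in the sources used here. The authors' deposited table also has log2 fold changes, p-values and adjusted p-values between numbered groups, per the file headers. The test is not given in the sources used here. Gene names were taken from the files, which name 2228 of the 6859 genes in the newly synthesized RNA table and 2221 of the 6805 in the total RNA table. Other genes are given by their systematic ID with the deposited description.

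Raw counts were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided) in R 4.3.3, with a single fit over the 8 libraries of a kind of RNA and the group as the only factor. The authors' constants served as scaling factors, and log2 fold changes are on that scale. Genes kept by edgeR's filterByExpr were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The tested contrasts were auxin minus DMSO in each strain, the difference of these changes between the strains, and the Med17 minus Med14 strain in DMSO. A joint fit of the 16 libraries tested the change of newly synthesized RNA minus that of total RNA. Standard errors (SE) are those of the log2 fold change, and normalized counts are given as mean ± SD with n = 2 unless stated. A comparison of single values of 2 against 2 libraries cannot go below an exact p of 0.333, so no such test was run.

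Gene lists were set against all other genes with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation. A self-contained test (fry) asked whether a list's genes moved on balance in 1 direction. Of 29 lists, 25 had at least 5 tested members and were tested, with Benjamini-Hochberg adjustment over the lists of a contrast. The lists were Mediator, ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, heat shock, general stress, Gcn4-type amino acid synthesis, methionine and sulfur, histones, G1/S and G2/M cell cycle, proteasome and RNA polymerase II subunits. The others were general factors with TFIID and SAGA, weak-acid and drug efflux, Yap1-type oxidative stress, mating, phosphate, iron, ergosterol, hexose transport and glucose-repressed, pyrimidine, nuclear-encoded respiration, translation factors, mRNA decay, snoRNA and snRNA, RNA polymerase III transcripts, the mitochondrial genome and S. pombe genes. The last list had 0 members in the tables. The tRNA genes of the mitochondrial genome were kept out of the RNA polymerase III list. Transfer RNA genes occur in near-identical copies, so counts of single tRNA genes are uncertain.

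The lists, the contrasts, the main scaling, the repeated fits below and the rule for named genes were fixed before the data were examined. The rule named the tagged genes in every group. Per auxin contrast it named the 8 lowest and 8 highest log2 fold changes among called genes with a mean count of at least 50 and the same direction in both replicate pairs. Where the main scaling called fewer than 5 genes in a direction there, it added 5 and 5 under TMM, which did not arise. Per difference contrast it named 5 and 5 in the same way, or all that passed where fewer did. Dubious reading frames and strain marker genes stayed out. Per list it named the 2 members with the highest mean count and, where the list passed its test, the 2 with the smallest p in its direction. Of these genes, those described are a selection. For every called gene named in a comparison of 2 groups, the libraries of the groups did not overlap. Chance alone gives this for a single gene with a probability of 0.333, but these genes were chosen by their calls in the same libraries. The separation is therefore no further support for them.

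The fits were repeated with TMM, median-of-ratios and total-count scaling, other filters on low counts, DESeq2 1.42.0 (Wald test), a log2 threshold of 1, a replicate block, fits of the 4 libraries of a strain, and each library left out in turn. Scaling by SCR1 with RPR1, scaling by mitochondrial genes, both libraries of newly synthesized RNA of the Med14 strain numbered 2 left out, GO terms of the deposited annotation, and a direct comparison of the auxin libraries were chosen after seeing the data. Libraries with the same number in the source labels deviated together from their group means (correlation across genes 0.124 to 0.276 over the strains and kinds of RNA), so the block is given where it changed a call. Both Med14 libraries numbered 2 carry titles numbered apart from the others. Replicates were checked for duplicates with a chi-square test of their counts. The chi-square per degree of freedom was 6.51 to 27.6 over the 8 groups, so no pair was a repeat deposit of the same library, and Pearson's r of their log counts was 0.984 to 0.992 across genes.

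The fit was tested on simulated counts in which known genes were changed. For the Med14 contrast of newly synthesized RNA, 95 of 100 genes changed by a log2 of 1 and 100 of 100 changed by 2 were called among 5990 genes, with 11 unchanged genes called. For the difference between strains these were 69 and 100 of 100, with 17 unchanged genes called. For total RNA, 91 and 100 of 100 were called in the Med14 contrast among 5550 genes, and 65 and 99 of 100 in the difference. For newly synthesized minus total RNA in the Med14 strain, 142 and 191 of 195 were called among 5593 genes. The simulated list of changed genes was called in both kinds of RNA, and 0 of 20 random lists were. Only 200 genes were changed in a kind of RNA, genes varied independently and the fit was given the true scaling factors. The simulation therefore could not test an error of the factors, a change of nearly all genes or correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.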

Results

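The data comprised 16 RNA libraries of budding yeast, 8 of newly synthesized RNA labelled for 6 min with 4tU and 8 of total RNA. Strains had a degron on Med14 or Med17 and received auxin or DMSO, with 2 biological replicates per group. By its title the study concerns how the architectural subunits of Mediator differ in their role in global transcription. Raw totals were 3.83 to 13.96 M counts per library for newly synthesized RNA and 3.30 to 8.84 M for total RNA. On the authors' normalized scale the newly synthesized RNA of the Med14 strain summed to 17.4 ± 0.371 M counts in DMSO and 4.09 ± 0.176 M with auxin (SD, n = 2), which is 23.5% of the DMSO level. In the Med17 strain it summed to 15.2 ± 0.527 M in DMSO and 2.56 ± 0.262 M with auxin, which is 16.8%. Total RNA was left at 79.0% in the Med14 strain, from 5.62 ± 0.0495 to 4.44 ± 0.209 M, and at 69.8% in the Med17 strain, from 6.24 ± 0.403 to 4.35 ± 0.120 M. In all 4 cases the gap between DMSO and auxin exceeded the spread between replicates, although 2 against 2 libraries cannot reach an exact p below 0.333.

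**Figure D1:**
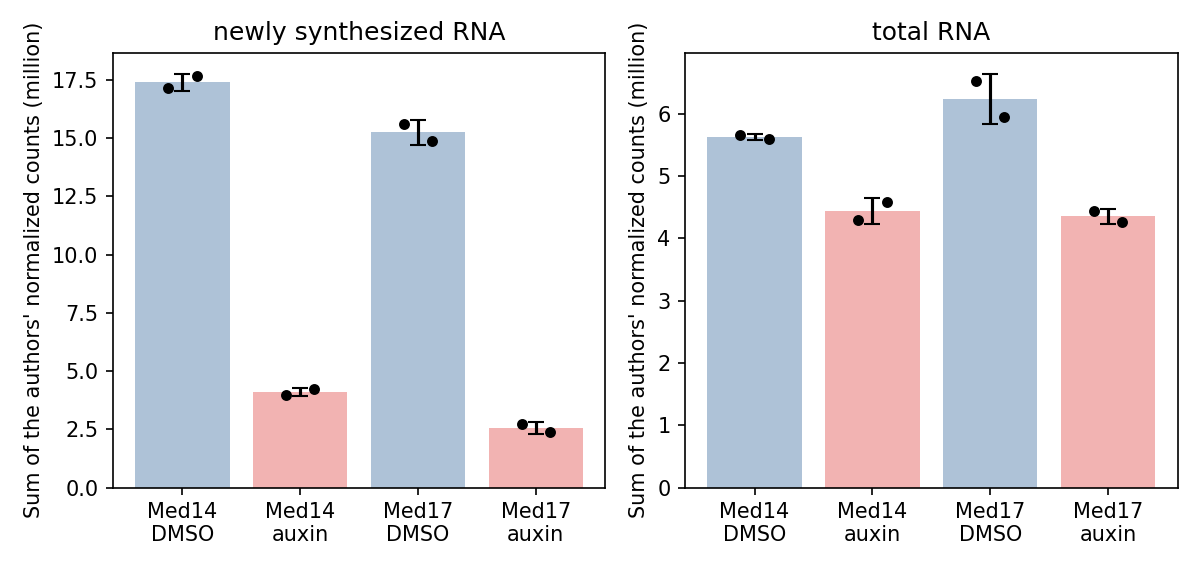
Sum of the authors' normalized counts per library in M, for newly synthesized RNA and for total RNA. Bars are means of 2 replicates, error bars are the SD and points are libraries; newly synthesized RNA fell to 23.5% (Med14) and 16.8% (Med17) of its DMSO level and total RNA to 79.0% and 69.8%.

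The tagged genes were examined in every group. RGR1, which encodes Med14 (YLR071C, chromosome XII, 275378 to 278626, sacCer3), had 3956 ± 394 normalized counts of newly synthesized RNA in DMSO and 1648 ± 84.8 with auxin in the Med14 strain, and 4134 ± 302 and 1107 ± 134 in the Med17 strain. SRB4, which encodes Med17 (YER022W, chromosome V, 198812 to 200875), had 2070 ± 276 and 728 ± 9.34 in the Med14 strain and 2199 ± 158 and 333 ± 22.3 in the Med17 strain. Newly synthesized RGR1 RNA thus fell with auxin in the Med14 and Med17 strains (log2 fold changes -1.26 and -1.90), but both values turned positive with TMM (0.60 and 0.75). SRB4 fell likewise (-1.51 and -2.72), with 0.36 and -0.074 under TMM. In total RNA, RGR1 went from 527 ± 55.3 to 466 ± 9.83 in the Med14 strain (-0.18, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.179) and from 637 ± 22.6 to 314 ± 25.8 in the Med17 strain (-1.02, adjusted p = 3.78e-06, but 0.20 with TMM). SRB4 total RNA went from 309 ± 19.4 to 191 ± 31.9 in the Med14 strain (-0.69, and 0.0027 with TMM) and from 344 ± 14.7 to 117 ± 28.9 in the Med17 strain (-1.55, and -0.33 with TMM). The degron acts on the protein, so these RNA levels do not check the labels.

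Auxin in the Med14 strain lowered newly synthesized RNA of nearly every kind of gene transcribed by RNA polymerase II. The phenylpyruvate decarboxylase gene YDR380W (chromosome IV, 1234218 to 1236125) fell from 2950 ± 251 to 39.7 ± 6.05 normalized counts. Its log2 fold change was -6.21 (SE 0.265, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.06e-11). The alpha-factor gene YGL089C (chromosome VII, 344791 to 345153) fell from 9286 ± 878 to 207 ± 20.4 (-5.49, SE 0.192, adjusted p = 3.39e-12). The aromatic aminotransferase gene YHR137W changed by a log2 fold change of -4.94, the ornithine transaminase gene CAR2 by -4.57 and the meiotic gene NDJ1 by -4.61. Among abundant transcripts, the ribosomal protein gene RPL10 (YLR075W, chromosome XII, 282927 to 283592) fell from 27620 ± 1891 to 3601 ± 427 (-2.94, SE 0.180, adjusted p = 9.35e-11). The glycolytic genes ENO2 (-3.31) and TDH3 (-3.18), the phosphate transporter gene PHO84 (-3.84) and the pheromone receptor gene STE3 (-4.02) fell by more than the median gene.

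Few transcripts rose in this comparison, and several were of low count. The tRNA gene tT(AGU)C rose by a log2 fold change of 1.44 (SE 0.367, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00120). The spore wall gene YOR242C rose from 135 ± 61.3 to 307 ± 53.8 (1.16, SE 0.259, adjusted p = 0.000364), and the kinase gene YDR523C by 1.28. The spore wall glucanosyltransferase gene YLR343W rose by 0.90 and the flocculin gene MUC1 by 0.90. The sporulation gene DIT2 rose by 1.04 (adjusted p = 0.00982), a call that was lost without DMSO replicate 1 (0.67) or auxin replicate 2 (0.77). By counting alone, reads of overlapping transcripts at these genes could not be excluded.

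Grouped by list, ribosomal protein genes lay below other genes in the Med14 strain, with 137 of 137 lower and a median of -2.98 (camera adjusted p = 2.75e-07). With an estimated correlation that list had an adjusted p = 0.849, and its TMM median was still negative (-1.11). All tested members were lower for glycolysis and fermentation (11 genes, median -3.23), Yap1-type genes (11, -3.19), phosphate (10, -2.85), heat shock (10, -2.58), Gcn4-type amino acid synthesis (9, -2.54), ergosterol (13, -2.52) and general stress (12, -2.46). The same held for translation factors (27, -2.11), G1/S genes (18, -2.10), mating (10, -2.03), methionine and sulfur (8, -2.03), respiration (16, -1.96) and G2/M genes (7, -1.89). Medians above that of all genes were found for the proteasome (22 genes, all lower, -1.60), ribosome biogenesis (23, all lower, -1.59), RNA polymerase II (12, all lower, -1.59), Mediator (18, all lower, -1.53), mRNA decay (22, all lower, -1.53) and general factors with TFIID and SAGA (27, all lower, -1.33). With TMM these 6 medians turned positive, from 0.26 for the proteasome to 0.54 for the general factors. Lower members numbered 68 of 70 for snoRNA and snRNA genes (-2.75), 12 of 13 for hexose transport (-2.06) and 5 of 6 for weak-acid and drug efflux (-2.52). The untested short lists had 4 of 4 histone, 4 of 4 iron and 2 of 2 pyrimidine genes lower. In all of these lists the counts adjusted over the list alone were the same.

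Transcripts made by other polymerases stood apart in the Med14 strain. RNA polymerase III transcripts had a median change of 0.23, with 7 lower and 8 higher of 134 (4 lower and 2 higher adjusted over the list alone), and their TMM median was 2.13. The mitochondrial genome had a median of 0.19, with 1 of 16 genes higher (0 adjusted over the list alone), and a TMM median of 2.02. TMM called 0 lower and 136 higher among the RNA polymerase III transcripts that passed its filter, and 0 and 12 in the mitochondrial genome. With mitochondrial scaling the medians of these lists were -0.099 and -0.037. With SCR1 and RPR1 scaling they were 0.99 (3 lower and 47 higher of 134) and 1.00 (0 and 10 of 15). Both lists lay above other genes by camera, both with an adjusted p = 0.0496 with an estimated correlation. SCR1, the RNA of the signal recognition particle (chromosome V, 441987 to 442508), was at 86450 ± 10160 in DMSO and 45170 ± 17890 with auxin (-0.94), but at 0.91 on the TMM scale. RPR1, the RNA of RNase P, changed by -0.63 on the authors' scale, by 1.22 with TMM and by 0.17 with SCR1 and RPR1 scaling, and its call was lost without DMSO replicate 1 (-0.44) or auxin replicate 1 (-0.37).

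Over all genes of this comparison, 5720 of 6072 were lower and 34 higher (edgeR quasi-likelihood, Benjamini-Hochberg), with a median log2 fold change of -1.86, quartiles of -2.30 and -1.49, and -1.85 for each replicate number. On the TMM scale, which assumes that the bulk of genes is constant, 1478 genes were lower and 1517 higher and the median was 0.022. The corresponding medians with median-of-ratios and total-count scaling were 0.0059 and 0.25. The count of higher genes was 64 without auxin replicate 1, 19 without auxin replicate 2, 19 with DESeq2 and 22 without both libraries numbered 2.

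**Figure D2:**
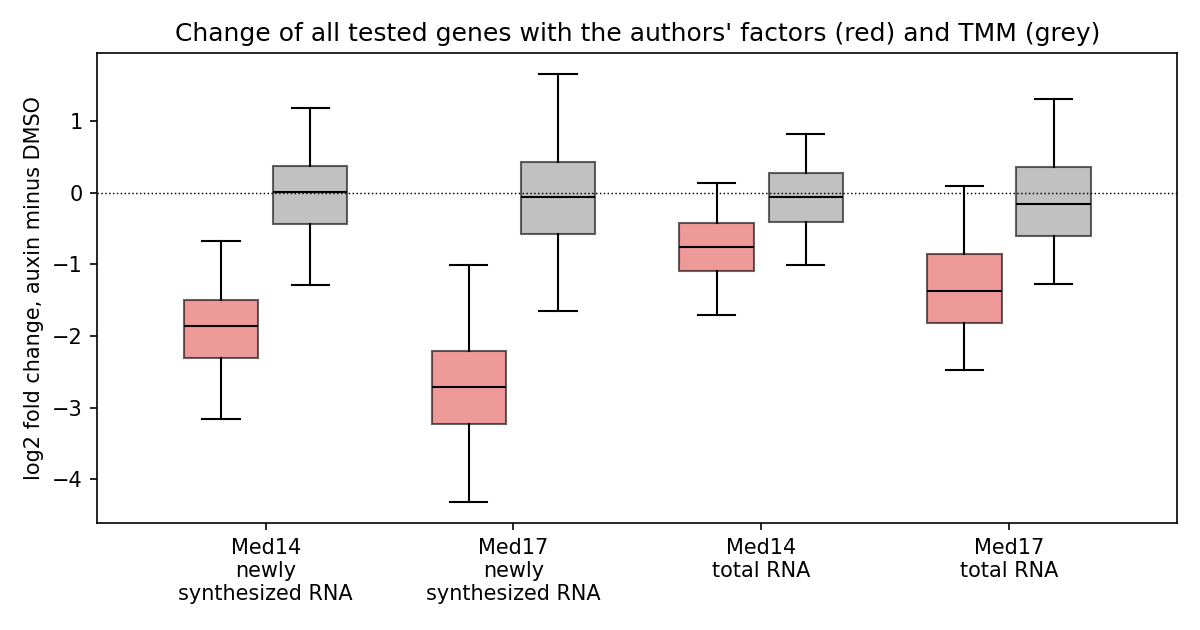
Log2 fold change, auxin minus DMSO, of all tested genes for both strains and kinds of RNA, with the authors' factors (red) and with TMM (grey). Boxes span the quartiles, lines are medians and whiskers run from the 5th to the 95th percentile; the medians of newly synthesized RNA were -1.86 and -2.71 with the authors' factors and 0.022 and -0.043 with TMM.

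With the authors' factors, auxin in the Med17 strain lowered newly synthesized RNA further. The NADPH oxidoreductase gene OYE3 (YPL171C, chromosome XVI, 226169 to 227371) fell from 12890 ± 434 to 9.52 ± 6.79 normalized counts (-10.45, SE 0.281, edgeR adjusted p = 3.55e-14). The nitroreductase-like gene HBN1 (YCL026C-B, chromosome III, 73405 to 73986) fell from 5672 ± 236 to 10.8 ± 6.05 (-9.07, SE 0.253, adjusted p = 3.55e-14). The glutathione transferase gene ECM4 changed by -8.36 and the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 from 6570 ± 996 to 46.4 ± 11.4 (-7.16). The trehalose phosphatase gene TPS2 changed by -4.08, the glycerol phosphate dehydrogenase gene GPD1 by -4.51 and the sulfite reductase gene MET5 by -3.98. RPL10 fell from 29120 ± 1296 to 3710 ± 819 (-2.97). STE3 changed by -4.30, while TDH3 (-2.57) and PHO84 (-2.60) were slightly positive with TMM (0.066 and 0.046).

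On the authors' scale 103 transcripts rose in the Med17 strain and 34 in the Med14 strain, and those of the Med17 strain were mainly tRNA and mitochondrial genes. The order turned with SCR1 and RPR1 scaling (92 and 122) and with total-count scaling (1503 and 2410). Without auxin replicate 1 of the Med17 strain its count was 61, and without auxin replicate 1 or 2 of the Med14 strain that of the Med14 strain was 64 or 19. The tRNA genes tG(GCC)P1 (2.92), tT(AGU)C (2.69) and tW(CCA)P (1.96) rose. So did the RNA polymerase III snoRNA snR52, from 124 ± 0.800 to 598 ± 206 (2.26, SE 0.327, edgeR adjusted p = 2.62e-06). The mitochondrial maturase-like gene Q0255 rose from 20.8 ± 6.29 to 126 ± 6.46 (2.57, SE 0.346, adjusted p = 1.05e-06). The spore genes YLR343W (49.1 ± 0.0538 to 257 ± 3.16, 2.39), YOR242C (1.75) and DIT2 (1.86) and the kinase gene YDR523C (1.17) rose as well. MUC1, higher in the Med14 strain, was lower in the Med17 strain (-2.34, SE 0.281), with 0.29 under TMM.

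RNA polymerase III transcripts rose as a group in the Med17 strain, with 77 of 134 higher and 1 lower (64 and 1 adjusted over the list alone). The median was 1.73, with a camera adjusted p = 0.0150 with an estimated correlation. Nuclear tRNA genes together made up only 0.00756% of the counts in DMSO and 0.145% with auxin, so single tRNA genes had few counts in DMSO. With a mean count of at least 50, 22 genes of any kind were called higher, against 103 in the main fit. Within the list, SCR1 had 55440 ± 74.9 in DMSO and 50320 ± 13420 with auxin (-0.14, edgeR adjusted p = 0.555, 2.49 with TMM). RPR1 rose by 0.52 (adjusted p = 0.0273) but lost its call without DMSO replicate 2 (0.41) or auxin replicate 1 (0.16), and was at -0.26 with mitochondrial scaling. The mitochondrial genome had 12 of 16 genes higher and 1 lower, a median of 1.72 and a camera adjusted p = 0.0345 with an estimated correlation. Its 2 members with the highest mean count lay far below that median, COX2 at -0.18 and COX3 at 0.29.

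Every tested member was again lower for most lists of RNA polymerase II genes. The medians were -4.72 for Yap1-type genes, -4.05 for general stress, -3.47 for methionine and sulfur, -3.30 for weak-acid and drug efflux (6 of 6), -3.24 for glycolysis, -2.88 for ribosomal proteins and -2.87 for heat shock. They were -2.83 for respiration, -2.77 for the proteasome, -2.71 for mating, -2.67 for phosphate, -2.64 for G2/M, -2.48 for general factors with TFIID and SAGA and -2.45 for G1/S genes. Medians nearer to 0 were those of Mediator (-2.38), ergosterol (-2.34), translation factors (-2.33), Gcn4-type genes (-2.32), RNA polymerase II (-2.27), mRNA decay (-2.19) and ribosome biogenesis (-1.64). With TMM these 7 medians turned positive, from 0.27 for Mediator to 1.03 for ribosome biogenesis, as did those of general factors with TFIID and SAGA (0.16), G1/S (0.20), G2/M (0.0045), hexose transport (0.016) and snoRNA and snRNA genes (0.11). NSR1, a nucleolar assembly factor, changed by -1.45 but was at 1.21 with TMM, and RPL3 changed by -2.03 but was at 0.62. Exceptions were 67 of 70 snoRNA and snRNA genes lower (-2.53), 12 of 13 hexose transport genes (-2.74) and 2 of 4 iron genes, while all 4 histone and both pyrimidine genes were lower. Adjusted over the list alone, the counts of these lists were the same, and none of them differed from other genes by camera (ribosomal proteins, adjusted p = 0.363).

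Of 6072 genes, 5771 were lower and 103 higher in the Med17 strain (edgeR quasi-likelihood, Benjamini-Hochberg), with a median of -2.71, quartiles of -3.23 and -2.21, and -2.67 and -2.73 for the replicate numbers. TMM gave 1841 lower, 1733 higher and a median of -0.043. Median-of-ratios and total-count scaling gave medians of -0.00575 and -0.11. Without auxin replicate 1, 61 genes were higher. Across genes, which are not independent replicates, the changes of the strains correlated with a Pearson's r of 0.644 and a Spearman's rho of 0.563 over 6072 genes. By mean count, the medians of the 5 expression classes, from the lowest, were -1.86, -1.96, -1.82, -1.75 and -1.93 in the Med14 strain and -2.80, -3.06, -2.76, -2.58 and -2.50 in the Med17 strain. The authors' deposited table holds comparisons of numbered groups whose identity the headers do not give. In the authors' deposited table, the pair closest to the Med14 contrast (median absolute difference 0.0145) had 5641 genes lower and 19 higher at an adjusted p under 0.05. The pair closest to the Med17 contrast in the authors' deposited table (0.0219) had 5762 lower and 74 higher.

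**Figure D3:**
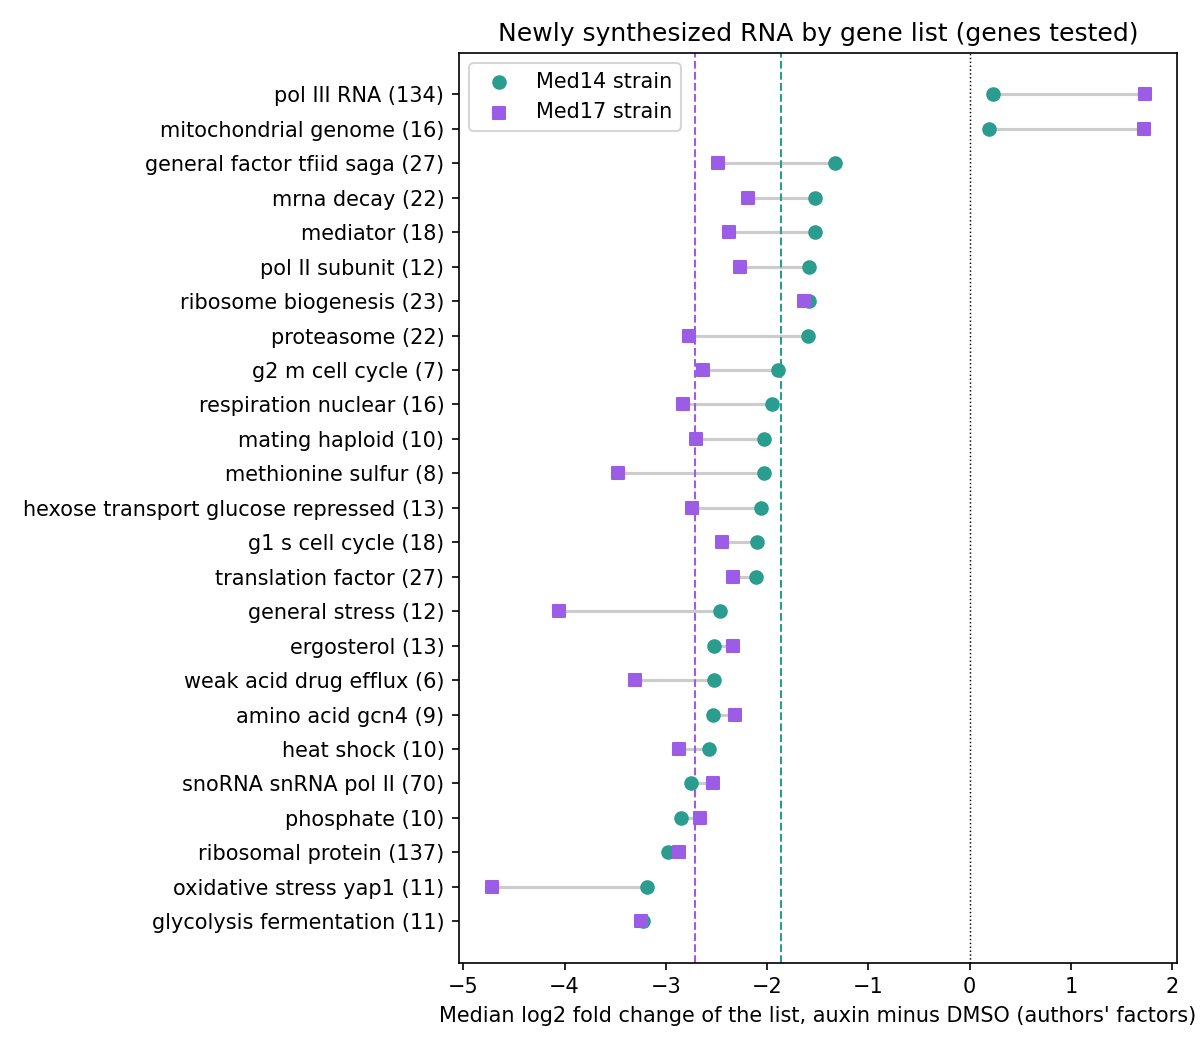
Median log2 fold change, auxin minus DMSO, of newly synthesized RNA per gene list with the authors' factors, with the number of genes tested in parentheses; circles are the Med14 strain, squares the Med17 strain, and dashed lines the medians of all genes (-1.86 and -2.71). Ribosomal proteins sat at -2.98 and -2.88 and the proteasome at -1.60 and -2.77, while RNA polymerase III transcripts sat at 0.23 and 1.73; with TMM the proteasome turned positive in the Med14 strain (0.26).

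The difference of these changes was then tested, Med14 change minus Med17 change. A positive value means a larger fall or smaller rise with Med17, and a negative value a smaller fall or larger rise. Genes for proteasome subunits fell more in the Med17 strain, with 20 of 22 called and a median difference of 1.22 (camera adjusted p = 0.00454; adjusted p = 0.689 with an estimated correlation). RPN11 (YFR004W, chromosome VI, 153393 to 154313) went from 2746 ± 42.7 to 977 ± 61.0 in the Med14 strain and from 3880 ± 29.6 to 396 ± 46.5 in the Med17 strain (difference 1.80, SE 0.197, edgeR adjusted p = 3.68e-06), and RPT2 differed by 1.85. General factors with TFIID and SAGA had 25 of 27 called higher (camera adjusted p = 0.0405; adjusted p = 0.689 with an estimated correlation), with a median of 0.80 below and a mean of 0.95 above the all-gene median of 0.82. TFG1 (1.59) and TAF2 (1.49) had the smallest p of that list, whose camera call was lost without DMSO replicate 2, auxin replicate 1 or auxin replicate 2 of the Med14 strain or auxin replicate 2 of the Med17 strain (adjusted p = 0.0665, 0.117, 0.0515 and 0.0536). Yap1-type genes had 7 of 11 higher and a median of 2.14 (camera adjusted p = 0.0234; adjusted p = 0.689 with an estimated correlation; 0.0846 without DMSO replicate 2 of the Med14 strain and 0.0588 with the replicate block), with OYE3 (6.36) and HBN1 (5.95). These differences were about as large as those of the strains in DMSO (Med17 minus Med14, median 1.89, OYE3 7.33), while with auxin OYE3 was at 4.58 (Med14) and 9.52 (Med17) normalized counts. Proteasome genes too were higher in Med17 DMSO (0.36, all genes -0.21), so a separate response is not shown. With TMM fewer members of these lists were called. It gave 11 proteasome genes higher and 1 lower (median 0.44), 5 and 1 of general factors with TFIID and SAGA (0.029), and 6 and 0 of Yap1-type genes (1.36). The drug transporter gene YBR008C differed by 5.41, MET5 by 2.63 and TPS2 by 2.04.

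Other lists had median differences under the all-gene median of 0.82. Ribosomal protein genes had a median difference of -0.12, with 10 of 137 lower and 6 higher (0 and 0 adjusted over the list alone; camera adjusted p = 6.43e-23; adjusted p = 0.689 with an estimated correlation). TMM called 122 ribosomal protein genes lower and 0 higher (median -0.90), 19 and 0 of ribosome biogenesis, 10 and 0 of ergosterol, 8 and 0 of phosphate, 13 and 0 of translation factor and 41 and 0 of snoRNA and snRNA genes. RPS31 (-0.83) and RPS12 (-1.07) differed, the latter not without DMSO replicate 1 of the Med14 strain (-0.76). Ribosome biogenesis had a median of 0.064, 2 lower and 2 higher of 23 (0 and 0 over the list alone), and NSR1 was at -0.89 (-0.64 and -0.57, not called, without DMSO replicate 1 of the Med14 strain or DMSO replicate 2 of the Med17 strain). Ergosterol genes had 5 lower and 2 higher of 13 (3 and 2 adjusted over the list alone) and a median of -0.18. The sterol desaturase gene ERG3 (YLR056W, chromosome XII, 253861 to 254958) went from 7007 ± 187 to 620.1 ± 89.0 in the Med14 strain and from 1586 ± 328 to 874 ± 116 in the Med17 strain (-2.64, SE 0.234, edgeR adjusted p = 3.85e-07), and ERG11 differed by -0.74. Phosphate genes had 4 lower and 2 higher of 10, a median of -0.35 and its smallest p at PHO84 (-1.24) and PHO5 (-1.12). Translation factors had 5 lower and 9 higher of 27 (5 and 8 over the list alone), a median of 0.39 and TEF1 at -1.10. Gcn4-type genes had a median of 0.16 (1 lower, 1 higher of 9) and snoRNA and snRNA genes -0.29 (8 and 3 of 70, 2 and 0 over the list alone). RNA polymerase III transcripts had 34 of 134 lower (1 over the list alone, -1.37) and the mitochondrial genome 8 lower and 1 higher of 16 (-1.54), with snR52 at -2.72. By camera all of these lists lay below other genes (adjusted p from 2.42e-61 to 0.00827), and with an estimated correlation their adjusted p = 0.450 to 0.689. With TMM the medians of ribosome biogenesis (-0.72), translation factors (-0.39) and Gcn4-type genes (-0.61) turned negative. With SCR1 and RPR1 scaling or mitochondrial scaling the medians of ribosomal proteins (0.86 and 0.44), ergosterol (0.84 and 0.42), phosphate (0.62 and 0.21) and snoRNA and snRNA genes (0.63 and 0.25) turned positive, and with the former that of the mitochondrial genome did too (0.082). The adenine deaminase gene YNL141W (-2.21) and the ribonucleotide reductase gene RNR1 (-1.35) also fell less in the Med17 strain.

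Of 6072 genes, 3619 had a positive and 199 a negative difference (edgeR quasi-likelihood, Benjamini-Hochberg), whereas TMM gave 1023 and 1092. The median difference was 0.82, and 0.81 for each replicate number, against 0.035 with TMM. Among the 199 were transcripts that rose in the Med17 strain, such as snR52 (2.26) and Q0255 (2.57). The count of 199 became 119 without DMSO replicate 2 and 106 without auxin replicate 1 of the Med17 strain, and 20 and 33 with SCR1 and RPR1 or mitochondrial scaling. With the former, ERG11, NSR1 and RPS31 were positive (0.24, 0.14 and 0.16). From the lowest to the highest of the 5 expression classes the median difference was 0.86, 1.09, 0.93, 0.76 and 0.46. Comparing the auxin libraries directly, 5161 genes were higher and 44 lower in the Med14 strain, with a median of 1.00.

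The strains already differed in DMSO, without auxin, most of all at Yap1-type oxidative stress genes. Levels of the tagged proteins in DMSO are not among these data. OYE3 had 81.2 ± 14.7 normalized counts of newly synthesized RNA in the Med14 strain and 12890 ± 434 in the Med17 strain, a log2 difference of 7.33 (SE 0.237, edgeR adjusted p = 8.87e-13), and 153 ± 103 and 2663 ± 418 in total RNA (4.12, SE 0.667, adjusted p = 0.00172). HBN1 differed by 5.68 in newly synthesized and 4.04 in total RNA, the nitroreductase gene FRM2 by 6.24 in newly synthesized RNA and OYE2 by 1.68. As a list, Yap1-type genes had 8 of 11 higher in newly synthesized RNA (median 1.89, camera adjusted p = 3.20e-12; adjusted p = 0.543 with an estimated correlation). In total RNA 10 were higher (1.82; adjusted p = 0.454 with an estimated correlation). Methionine and sulfur genes were higher too, 7 of 8 with a median of 0.86 and 7 of 7 with 1.01, among them MET5 (8110 ± 163 and 33260 ± 5858, 2.04) and MET1 (2.10). Heat shock genes had 5 of 10 higher (0.31) and 9 in total RNA (0.62), among them the inducible chaperone gene SSA4 (2.59 and 2.29). Proteasome genes had 11 of 22 higher (13 over the list alone, 0.36) and 20 in total RNA (0.55), and the drug transporter gene ATR1 was higher (2.90).

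Lower in the Med17 strain in DMSO were ribosome biogenesis (22 of 23 in newly synthesized RNA, 23 over the list alone, -0.80; 15 in total RNA, -0.56) and ribosomal proteins (123 of 137, 129 over the list alone, -0.73). Ribosomal proteins did not share this in total RNA, with 0 lower and 6 higher of 137 (0 and 4 over the list alone) and a median of 0.030 (-0.051 with TMM). The mitochondrial genome (8 of 16, 12 over the list alone, -1.73) and RNA polymerase III transcripts (22 of 134, 12 over the list alone, -1.15) were lower in newly synthesized RNA, so their rises with auxin in the Med17 strain started from a lower level. The mitochondrial call was lost without DMSO replicate 1 of the Med14 strain or of the Med17 strain (adjusted p = 0.473 and 0.0692). In total RNA the medians of these lists were -0.12 and -0.25. The snoRNA and snRNA genes were lower in newly synthesized RNA as well (48 of 70, 57 over the list alone, -0.92; in total RNA 2 of 73, 1 over the list alone, -0.26). So were ergosterol (10 of 13, -0.66; in total RNA 2, 3 over the list alone, -0.0088), respiration (13 of 16, 14 over the list alone, -0.65) and G1/S genes (11 of 18, 12 over the list alone, -0.48). In newly synthesized RNA all lists named for the strains in DMSO passed camera and had an adjusted p = 0.543 to 0.725 with an estimated correlation. In total RNA 10 lists passed, namely Yap1-type, methionine and sulfur, heat shock, proteasome and Gcn4-type genes above other genes, and ribosome biogenesis, G1/S, respiration, snoRNA and snRNA genes and RNA polymerase III transcripts below them. They had an adjusted p = 0.454 to 0.750 with an estimated correlation. Without DMSO replicate 1 of the Med14 strain the snoRNA and snRNA call and the RNA polymerase III call were lost in total RNA (adjusted p = 0.289 and 0.766), the latter also with TMM (0.220). The medians of the lists that passed kept their sign with TMM but not with the other references. Those of newly synthesized ergosterol (0.035), respiration (0.051) and G1/S RNA (0.21) turned positive with SCR1 and RPR1 scaling. With mitochondrial scaling the same lists (0.58, 0.59 and 0.76), ribosomal proteins (0.51), ribosome biogenesis (0.47), snoRNA and snRNA genes (0.30) and RNA polymerase III transcripts (0.069) were positive. In total RNA the medians of Gcn4-type genes (-0.066) and ribosomal proteins (-0.39) turned negative with SCR1 and RPR1 scaling, and that of ergosterol genes (0.065) turned positive with mitochondrial scaling. By gene, HSP12, a stress-induced membrane protein gene, had 795 ± 107 and 84.5 ± 55.1 (-3.20; total RNA -3.17), the cell wall mannoprotein gene TIR1 differed by -3.53, ERG3 by -2.15, NSR1 by -1.46 and the fatty acid desaturase gene OLE1 by -1.63 in total RNA.

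In newly synthesized RNA 1466 genes were lower and 367 higher in the Med17 strain (edgeR quasi-likelihood, Benjamini-Hochberg; median -0.21), against 1083 and 825 with TMM and 601 higher with the replicate block. In total RNA 328 were lower and 545 higher (median 0.076), against 537 and 501. In newly synthesized RNA the counts were 904 lower without DMSO replicate 2 of the Med14 strain, 555 lower and 201 higher without DMSO replicate 2 of the Med17 strain, and 38 lower with SCR1 and RPR1 scaling, where the median was 0.48. Mitochondrial scaling gave 28 lower and 4291 higher and a median of 1.02. In total RNA the median was -0.35 with SCR1 and RPR1 and -0.070 with total-count scaling, and the counts were 206 and 280 without DMSO replicate 1 and 112 and 314 without DMSO replicate 2 of the Med14 strain, and 86 and 309 without DMSO replicate 2 of the Med17 strain.

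**Figure D4:**
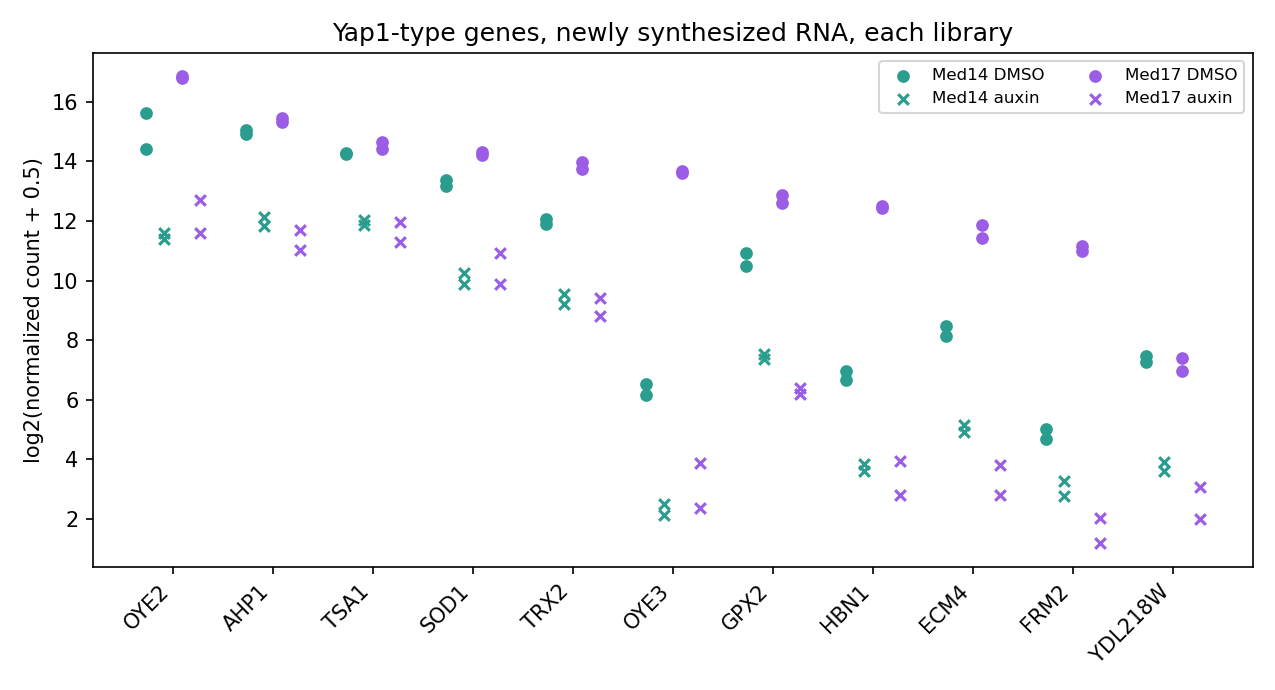
Newly synthesized RNA of the 11 tested Yap1-type genes, as log2 of the normalized count plus 0.5 in each library (authors' factors); circles are DMSO, crosses auxin, green the Med14 and purple the Med17 strain. OYE3 was higher in the Med17 than in the Med14 DMSO libraries by a log2 difference of 7.33, and averaged 4.58 (Med14) and 9.52 (Med17) normalized counts with auxin.

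Total RNA of the Med14 strain changed less than newly synthesized RNA, and a few transcripts rose. YDR380W fell from 429.9 ± 51.4 to 39.0 ± 25.7 normalized counts (-3.41, SE 0.368, edgeR adjusted p = 2.10e-05), and YHR137W (-2.67), NDJ1 (-2.83), the endoplasmic reticulum membrane protein gene WSC4 (-2.65), the B-type cyclin gene CLB1 (-2.62), STE3 (-2.46) and PHO84 (-2.34) fell strongly. HRP1, which encodes a cleavage factor subunit (YOL123W, chromosome XV, 87844 to 89448), rose from 1439 ± 87.6 to 4192 ± 142 (1.54, SE 0.147, adjusted p = 1.28e-05). The sporulation genes YOR242C (2.19), YLR343W (2.00) and SPO21 (1.90) and the tRNA gene tW(CCA)P (1.80) rose too. Ribosomal protein transcripts had a median of -0.053 and 34 of 137 lower (29 over the list alone; RPL8A -0.74), above other genes by camera (adjusted p = 1.37e-17; adjusted p = 0.987 with an estimated correlation), and their TMM median was positive (0.64). RNA polymerase III transcripts had 27 of 69 higher (26 over the list alone), a median of 1.36 and an adjusted p = 0.0344 with an estimated correlation. SCR1 (0.053, adjusted p = 0.783; 0.74 with TMM) and RPR1 (-0.067, adjusted p = 0.805; 0.61 with TMM) did not pass, though SCR1 did without DMSO replicate 1 (0.41) and RPR1 without DMSO replicate 1 (0.52) or 2 (-0.48). For snoRNA and snRNA genes 29 of 73 were lower (24 over the list alone). Their median (-0.82) and mean (-0.93) lay below the all-gene median, while camera placed them above other genes (adjusted p = 0.00117; adjusted p = 0.987 with an estimated correlation). That call was lost without DMSO replicate 2 of the Med14 strain or either auxin library of the Med17 strain (adjusted p = 0.139, 0.155 and 0.130). The mitochondrial genome had 4 of 30 higher (0 over the list alone; 0.31; adjusted p = 0.0991 with an estimated correlation).

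Of 5625 genes, 4225 were lower and 91 higher (edgeR quasi-likelihood, Benjamini-Hochberg; median -0.76, and -0.65 and -0.85 for the replicate numbers), against 1073 and 1054 and a median of -0.061 with TMM. Median-of-ratios and total-count scaling gave medians of -0.00894 and -0.41, and the count of higher genes was 53 without auxin replicate 2.

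Total RNA of the Med17 strain showed larger changes. OYE3 fell from 2663 ± 418 to 150.3 ± 30.8 (-4.15, SE 0.659, edgeR adjusted p = 6.51e-05), HBN1 by -4.25, the sulfiredoxin gene YKL086W by -4.05, TPS2 by -1.92 and RPL3 by -1.30 (0.042 with median-of-ratios scaling). Higher with auxin were HRP1 (951 ± 185 to 4598 ± 571, 2.28, SE 0.151, adjusted p = 2.18e-07), YLR343W (3.28), YOR242C (2.82), SPO21 (2.48), the ubiquitin ligase gene YNL008C (1.95), snR52 (2.56), tG(GCC)P1 (3.14) and tW(CCA)P (2.68). RNA polymerase III transcripts had 64 of 69 higher, a median of 2.59 and an adjusted p = 0.0108 with an estimated correlation, while SCR1 (333500 ± 13240 and 333000 ± 11870, adjusted p = 0.992) and RPR1 (0.28, adjusted p = 0.285) did not pass, and both were positive with TMM (SCR1 1.22). Ribosomal protein transcripts had 36 of 137 lower and 1 higher (28 and 1 over the list alone), a median of 0.0028, a mean of -0.18, a TMM median of 1.23 and medians of -0.12 and -0.095 with SCR1 and RPR1 or mitochondrial scaling (camera above other genes, adjusted p = 1.47e-41; adjusted p = 0.623 with an estimated correlation). Ribosome biogenesis (17 of 23 lower, -0.70), translation factors (21 of 27, 19 over the list alone, -0.48) and snoRNA and snRNA genes (25 lower and 2 higher of 73, 21 and 0 over the list alone, -0.23) fell less than other genes by camera, and their medians were positive with TMM (0.53, 0.74 and 1.04). Their adjusted p = 0.0187, 0.0223 and 2.94e-20, and 0.917, 0.917 and 0.386 with an estimated correlation. Proteasome genes, all 22 lower with a median of -1.46, fell more (camera adjusted p = 0.0304; adjusted p = 0.917 with an estimated correlation), among them RPN11 (-1.92) and PRE3 (-1.82). The mitochondrial genome had 1 lower and 2 higher of 30 (0 and 0 over the list alone; 0.19; adjusted p = 0.115 with an estimated correlation). Without auxin replicate 1 or DMSO replicate 2 of this strain the ribosome biogenesis (adjusted p = 0.0654 and 0.750), proteasome (0.0654 and 0.0934) and translation factor calls (0.0659 and 0.188) were lost, the proteasome call also without either auxin library of the Med14 strain (0.0545 and 0.0553). With the replicate block the ribosome biogenesis and proteasome calls were lost (0.100 and 0.109).

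Of 5625 genes, 4914 were lower and 136 higher (edgeR quasi-likelihood, Benjamini-Hochberg; median -1.38, and -1.41 and -1.32 for the replicate numbers), against 1911 and 1469 and a median of -0.16 with TMM. Median-of-ratios and total-count scaling gave medians of -0.034 and -0.86. The 5 expression classes, from the lowest, had medians of -0.98, -0.94, -0.80, -0.68 and -0.38 in the Med14 strain and -1.63, -1.70, -1.51, -1.25 and -0.67 in the Med17 strain. Across 5625 genes, which are not independent replicates, the changes of the strains correlated with a Pearson's r of 0.700 and a Spearman's rho of 0.669. In the authors' deposited table the pairs of numbered groups closest to these contrasts (median absolute differences 0.0252 and 0.0447) had 3853 genes lower and 85 higher, and 4838 lower and 140 higher, at an adjusted p under 0.05.

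The difference of the changes in total RNA went the same way as in newly synthesized RNA for several groups. Proteasome genes had 20 of 22 falling more in the Med17 strain (21 over the list alone; median 0.91; camera adjusted p = 8.89e-05; adjusted p = 0.556 with an estimated correlation), among them RPN11 (1.51, SE 0.159, edgeR adjusted p = 0.000229) and RPT3 (1.23). Methionine and sulfur genes had 6 of 7 (1.05; adjusted p = 0.010; adjusted p = 0.556 with an estimated correlation), among them MET5 (1.56) and MET22 (1.53). Both lists were higher in Med17 DMSO (0.55 and 1.01, all genes 0.076), with the same limit. The membrane stress gene HSP30 fell in the Med17 strain from 358 ± 33.1 in DMSO to 47.6 ± 5.68 with auxin. Its difference of the changes was 4.02 (SE 0.271, edgeR adjusted p = 2.80e-05), which is more than this fall alone, and HBN1 differed by 3.89. OLE1 (-1.78), ERG3 (-1.62) and RNR1 (-1.07) fell less in the Med17 strain. NSR1 differed by -0.73, a call lost without any single library (-0.83 to -0.43) other than DMSO replicate 1 of the Med17 strain. Lists below other genes by camera included ribosomal proteins (-0.033; 0 lower and 4 higher of 137, 0 and 2 over the list alone), ribosome biogenesis (-0.011; 1 and 0 of 23, 0 and 0 over the list alone), phosphate (-0.077; 2 and 1 of 10, 0 and 0 over the list alone) and ergosterol (-0.037; 2 and 0 of 13, 1 and 0 over the list alone), all with an adjusted p = 0.556 with an estimated correlation. With SCR1 and RPR1 scaling the medians of ribosomal proteins (0.00093) and ribosome biogenesis (0.032) were positive. Below other genes by camera were also snoRNA and snRNA genes (-0.56; 3 and 0 of 73, 0 and 0 over the list alone; adjusted p = 0.526 with an estimated correlation) and RNA polymerase III transcripts (-1.09; 4 and 0 of 69, 0 and 0 over the list alone; adjusted p = 0.188 with an estimated correlation). Of 5625 genes, 2322 had a positive and 69 a negative difference (edgeR quasi-likelihood, Benjamini-Hochberg), against 337 and 473 with TMM. The median difference was 0.54, with 0.69 and 0.39 for the replicate numbers, and 0.020 with TMM. The 2322 became 1510 without DMSO replicate 1 and 1408 without auxin replicate 1 of the Med14 strain. The 69 became 112 without DMSO replicate 1, 41 without DMSO replicate 2 and 45 without auxin replicate 2 of the Med17 strain. SCR1 and RPR1 scaling gave 31 and 0.

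Newly synthesized RNA was compared with total RNA of the same strains in the joint fit. In the Med14 strain the alpha-factor gene YGL089C changed by -4.07 more in newly synthesized than in total RNA (SE 0.223, edgeR adjusted p = 1.54e-09), the snoRNA gene SNR17B by -3.87, the pyruvate decarboxylase gene YLR044C by -3.57 and RPS15 by -3.38. In the Med17 strain OYE3 changed by -6.29 more (SE 0.935, adjusted p = 1.08e-05) and TDH1 by -5.04, while Q0255 (2.37) and the mitochondrial gene OLI1 (0.77, adjusted p = 0.0355) went the other way. OLI1 lost its call without newly synthesized DMSO replicate 1 (0.64) or auxin replicate 1 (0.62) or total DMSO replicate 1 (0.74), DMSO replicate 2 (0.80) or auxin replicate 2 (0.70) of the Med17 strain. Of 5974 genes, 4810 had a negative and 1 a positive difference of newly synthesized minus total RNA change in the Med14 strain (edgeR quasi-likelihood, Benjamini-Hochberg, median -1.04). The Med17 strain had 5084 and 16 (-1.34). With TMM these became 648 and 218 (median 0.13) and 874 and 950 (0.10), and with total-count scaling 305 and 3194 (0.70) and 326 and 3184 (0.72). The 16 became 9 without newly synthesized DMSO replicate 2, 4 without newly synthesized auxin replicate 1 and 7 without total RNA DMSO replicate 1 of the Med17 strain. The 1 in the Med14 strain became 6 with the replicate block, 5 without newly synthesized DMSO replicate 1, 3 without total DMSO replicate 1, 2 without either total auxin library, and 0 without newly synthesized DMSO replicate 2, newly synthesized auxin replicate 2 or total DMSO replicate 2. Across 5595 genes, which are not independent replicates, the changes of newly synthesized and total RNA correlated with a Pearson's r of 0.605 and a Spearman's rho of 0.538 in the Med14 strain and 0.691 and 0.628 in the Med17 strain.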

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

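The comparisons of the strains stood out because the difference of the auxin effects was itself tested; the weighing tests below were chosen after the result was seen, except those on carried-over RNA and on reads of paralogs in newly synthesized RNA. The bounds of the tests on the baseline difference and on a recent response were also revised after their values were seen, and both revisions turned an exclusion into an open result. The test on carried-over RNA was set aside after its values in DMSO were seen, and the bound of the test on RNA polymerase III genes and the authors' factors was revised likewise, which turned an open result into an exclusion for the gap to SCR1 and RPR1. The bound on the authors' factors and the larger fall was revised as well, which turned an exclusion into an open result. Med14 change minus Med17 change was positive for 3619 genes and negative for 199 in newly synthesized RNA (edgeR quasi-likelihood, Benjamini-Hochberg). In total RNA the counts were 2322 and 69. The 199 became 119 without DMSO replicate 2 and 106 without auxin replicate 1 of the Med17 strain. The 2322 became 1510 without DMSO replicate 1 and 1408 without auxin replicate 1 of the Med14 strain, and the 69 became 112, 41 and 45 without DMSO replicate 1, DMSO replicate 2 and auxin replicate 2 of the Med17 strain.

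Gene lists whose difference passed camera in newly synthesized RNA had medians, Med14 change minus Med17 change, of 2.14 (Yap1-type), 1.22 (proteasome), 0.80 (general factors with TFIID and SAGA), 0.39 (translation factors), 0.16 (Gcn4-type) and 0.064 (ribosome biogenesis). Below 0 were ribosomal proteins (-0.12), ergosterol (-0.18), snoRNA and snRNA (-0.29), phosphate (-0.35), RNA polymerase III transcripts (-1.37) and the mitochondrial genome (-1.54). In total RNA the medians were 1.05 for methionine and sulfur, 0.91 for the proteasome, 0.21 for translation factors, 0.19 for the mitochondrial genome, 0.11 for G1/S and 0.083 for Gcn4-type genes. Those below 0 were ribosome biogenesis (-0.011), ribosomal proteins (-0.033), ergosterol (-0.037), phosphate (-0.077), snoRNA and snRNA (-0.56) and RNA polymerase III transcripts (-1.09). With TMM the medians of translation factors, Gcn4-type and ribosome biogenesis genes turned negative in both kinds of RNA (-0.39, -0.61 and -0.72; -0.32, -0.45 and -0.55), as did G1/S (-0.41) and the mitochondrial genome (-0.32) in total RNA. The newly synthesized RNA medians of ribosomal proteins, ergosterol, snoRNA and snRNA and phosphate genes turned positive with SCR1 and RPR1 scaling (0.86, 0.84, 0.63 and 0.62) and with mitochondrial scaling (0.44, 0.42, 0.25 and 0.21), and the mitochondrial genome with the former (0.082). In total RNA Gcn4-type and G1/S genes turned negative with mitochondrial scaling (-0.069 and -0.071), and ribosomal proteins and ribosome biogenesis positive with SCR1 and RPR1 scaling (0.00093 and 0.032). With an estimated correlation the lists had an adjusted p = 0.450 to 0.689 in newly synthesized and 0.188 to 0.788 in total RNA.

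With the authors' factors newly synthesized ribosomal protein RNA fell alike in both strains, with a median difference of -0.12, while the median gene fell more with Med17. The like fall depended on those factors, since this median was 0.86 with SCR1 and RPR1 scaling, 0.44 with mitochondrial scaling and -0.90 with TMM, below the all-gene medians of 1.80, 1.40 and 0.035. An error of the authors' factors could not by itself make the gap between ribosomal protein genes and the median gene, since a factor moves all genes alike. The gap was -0.94, with -1.09 and -0.74 for the replicate numbers. It restates the pattern and is no separate test of such an error. Such an error as the whole cause of the larger fall itself cannot be told apart from a true larger fall. The median difference was 1.40 with the lower of the reference scalings, but SCR1 and RPR1 differed between the strains themselves (-0.80 and -1.15). A floor set by carry-over of unlabelled RNA cannot be told apart from a like fall. In Med17 auxin the 5th percentile over genes of newly synthesized over total signal was 2.77 times the ribosomal protein median, but it was also 1.66 (Med14) and 1.98 (Med17) times that median in DMSO. There the ribosomal protein median was 1.20 and 0.727, against 0.156 and 0.0962 with auxin, so the same outcome arose where no such floor held. The strains' difference in DMSO cannot be told apart from a difference in the response. The reason is that the gap in the auxin libraries was -0.39, with -0.59 and -0.23 for the replicate numbers. The subunit depleted stays an open biological explanation.

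Reads at tRNA and other RNA polymerase III genes rose with auxin in both kinds of RNA of the Med17 strain and in total RNA of the Med14 strain (0 lower and 27 higher of 69, median 1.36; adjusted p = 0.0344 with an estimated correlation). Of 134 in newly synthesized RNA of the Med14 strain, 7 were lower and 8 higher (4 and 2 over the list alone), but 3 and 47 with SCR1 and RPR1 scaling and 0 and 136 with TMM, whose filter kept more of these genes. Reads of the added S. pombe cells, with factors that follow those cells, were argued against under that condition by a median rise of 1.73 in the Med17 strain, which such reads would hold near 0. An error of the authors' factors as the whole cause of the gap to SCR1 and RPR1 was argued against, since it would move them as much as the list. The list median exceeded RPR1 by 1.20 (SE of the gene 0.216) and SCR1 by 1.87 (SE 0.230) in newly synthesized RNA, and by 2.31 (SE 0.241) and 2.59 (SE 0.172) in total RNA. Such an error as the whole cause of the rise itself cannot be told apart from a true rise. The lowest list median was 0.93 over the reference scalings and kinds of RNA, but RPR1 itself was called in newly synthesized RNA. In newly synthesized RNA the list was lower in the Med17 strain in DMSO, with a median of -1.15, against a difference of the changes of -1.37. A true rise of these transcripts stays open too. Counts were low, with nuclear tRNA genes at 0.00756% of the newly synthesized RNA counts in Med17 DMSO and 0.145% with auxin.

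Yap1-type genes were higher in the DMSO libraries of the Med17 strain. A single Med17 culture was argued against, since at least 10 of 11 members were higher in both Med17 than in both Med14 replicates in each kind of RNA. Reads shared by paralogs were argued against for OYE3 in newly synthesized RNA, where OYE2 had 0.230 times its log2 difference. For total RNA they cannot be told apart from a true difference of OYE3, since this ratio was 0.463 (SE 0.0993). A response that began in the last minutes cannot be told apart from a standing difference, since the median excess in newly synthesized over total RNA was 0.17 with quartiles of -0.15 and 1.29. With auxin the list had a median of 0.28 (Med14 minus Med17), under the all-gene median of 1.00, so its larger fall with Med17 went with the higher level in DMSO. The tagged subunit and other differences between the strains stay open as biological explanations.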

How the results depend on the processing

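All values are log2 fold changes or counts, with new for newly synthesized RNA, and only changed results are printed. TMM and median-of-ratios factors set the bulk of genes near no change by construction; for the other changes the cause was not tested. Scaling by SCR1 with RPR1 or by mitochondrial genes and leaving out both new Med14 libraries numbered 2 were chosen after seeing the data. With TMM scaling, the genes called numbered 1478 lower and 1517 higher (new Med14), 1841 lower and 1733 higher (new Med17), 1092 lower and 1023 higher (new Med14 minus Med17 change), 825 higher (new strains in DMSO) and 1073 lower and 1054 higher (total Med14). Called genes numbered 1911 lower and 1469 higher (total Med17), 473 lower and 337 higher (total Med14 minus Med17 change), 537 lower (total strains in DMSO), 648 lower and 218 higher (new minus total Med14) and 874 lower and 950 higher (new minus total Med17). Medians of all genes came to 0.022 (new Med14), -0.043 (new Med17), 0.035 (new Med14 minus Med17 change), -0.030 (new strains in DMSO), -0.061 (total Med14), -0.16 (total Med17), 0.020 (total Med14 minus Med17 change), 0.13 (new minus total Med14) and 0.10 (new minus total Med17). For new Med14 the sign turned at RGR1 0.60, SRB4 0.36, SCR1 0.91, RPR1 1.22, TFG1 0.76 and RPN11 0.37. For new Med17 the sign turned at RPL3 0.62, NSR1 1.21, RGR1 0.75, TDH3 0.066, PHO84 0.046 and MUC1 0.29. For total Med14 the sign turned at SRB4 0.0027 and RPN11 0.29. For total Med17 the sign turned at RGR1 0.20. Lists past the test numbered 16 (new Med14), 12 (new Med17) and 7 (total Med14). For snoRNA and snRNA genes (total Med14) the direction turned, with an adjusted p of 0.775. With median-of-ratios scaling, the genes called numbered 1517 lower and 1445 higher (new Med14), 1713 lower and 1836 higher (new Med17), 1187 lower and 874 higher (new Med14 minus Med17 change), 861 higher (new strains in DMSO) and 927 lower and 1185 higher (total Med14). Called genes numbered 1460 lower and 1711 higher (total Med17), 581 lower and 273 higher (total Med14 minus Med17 change), 530 lower (total strains in DMSO), 724 lower and 112 higher (new minus total Med14) and 1006 lower and 673 higher (new minus total Med17). Medians of all genes came to 0.0059 (new Med14), -0.0057 (new Med17), -0.017 (new Med14 minus Med17 change), -0.019 (new strains in DMSO), -0.0089 (total Med14), -0.034 (total Med17), -0.050 (total Med14 minus Med17 change), 0.064 (new minus total Med14) and 0.012 (new minus total Med17). RGR1 0.59, SRB4 0.35, SCR1 0.90, RPR1 1.21, TFG1 0.75 and RPN11 0.36 turned sign (new Med14). RPL3 0.65, NSR1 1.25, RGR1 0.78, TDH3 0.10, PHO84 0.083 and MUC1 0.33 turned sign (new Med17). RPL8A 0.0048, SRB4 0.055 and RPN11 0.34 turned sign (total Med14). RPL3 0.042 and RGR1 0.32 turned sign (total Med17). With total-count scaling, the genes called numbered 990 lower and 2410 higher (new Med14), 2045 lower and 1503 higher (new Med17), 649 lower and 1962 higher (new Med14 minus Med17 change), 858 higher (new strains in DMSO) and 2536 lower and 417 higher (total Med14). Called genes numbered 516 higher (total Med17), 130 lower and 1212 higher (total Med14 minus Med17 change), 557 lower and 307 higher (total strains in DMSO), 305 lower and 3194 higher (new minus total Med14) and 326 lower and 3184 higher (new minus total Med17). Over all genes the median came to 0.25 (new Med14), -0.11 (new Med17), 0.33 (new Med14 minus Med17 change), -0.016 (new strains in DMSO), -0.41 (total Med14), -0.86 (total Med17), -0.070 (total strains in DMSO), 0.70 (new minus total Med14) and 0.72 (new minus total Med17). For new Med14 the sign turned at RGR1 0.83, SRB4 0.58, SCR1 1.139, RPR1 1.45, TFG1 0.99 and RPN11 0.60. For new Med17 the sign turned at RPL3 0.55, NSR1 1.13, RGR1 0.67 and MUC1 0.22. With a mean count of at least 50, the genes called numbered 12 higher (new Med14), 22 higher (new Med17), 47 higher (total Med14), 41 higher (total Med17) and 9 higher (new minus total Med17). Medians of all genes came to -1.87 (new Med14) and 0.83 (new Med14 minus Med17 change). With DESeq2, the genes called numbered 19 higher (new Med14). With SCR1 and RPR1 scaling, the genes called numbered 122 higher (new Med14), 20 lower (new Med14 minus Med17 change) and 38 lower (new strains in DMSO). Called genes numbered 1470 lower and 36 higher (total Med14), 0 lower and 31 higher (total Med14 minus Med17 change) and 38 lower and 31 higher (total strains in DMSO). Medians of all genes came to -1.03 (new Med14), -2.86 (new Med17), 1.80 (new Med14 minus Med17 change), 0.48 (new strains in DMSO), -1.51 (total Med17) and -0.35 (total strains in DMSO). For new Med14 the sign turned at RPR1 0.17. For new Med14 minus Med17 change the sign turned at ERG11 0.24, NSR1 0.14 and RPS31 0.16. With mitochondrial scaling, the genes called numbered 21 higher (new Med14), 53 higher (new Med17) and 33 lower (new Med14 minus Med17 change). Called genes numbered 28 lower and 4291 higher (new strains in DMSO), 511 higher (total Med14 minus Med17 change) and 177 lower (total strains in DMSO). The all-gene median came to -2.06 (new Med14), -3.49 (new Med17), 1.40 (new Med14 minus Med17 change), 1.02 (new strains in DMSO), -1.05 (total Med14) and -1.49 (total Med17). RPR1 -0.26 turned sign (new Med17). RNR1 0.019 turned sign (new strains in DMSO). With both new Med14 libraries numbered 2 left out, the genes called numbered 22 higher (new Med14) and 852 lower and 243 higher (new strains in DMSO). Over all genes the median came to -1.86 (new Med14) and 0.83 (new Med14 minus Med17 change). With no filter on low counts, the genes called numbered 209 higher (total Med17). Medians of all genes came to -1.81 (new Med14), -2.66 (new Med17), 0.81 (new Med14 minus Med17 change) and -1.31 (total Med17). With a log2 threshold of 1, the genes called numbered 100 lower and 2172 higher (new Med14 minus Med17 change), 346 lower and 115 higher (new strains in DMSO) and 1720 lower and 54 higher (total Med14). Called genes numbered 25 lower and 903 higher (total Med14 minus Med17 change), 59 lower and 122 higher (total strains in DMSO) and 2960 lower (new minus total Med14). With the replicate block, the genes called numbered 601 higher (new strains in DMSO) and 6 higher (new minus total Med14). With fry, lists past the test numbered 23 (new Med14), 25 (new Med17), 23 (total Med14), 22 (total Med17) and 6 (total strains in DMSO). With an estimated correlation, lists past the test numbered 0 (new Med14 minus Med17 change), 0 (new strains in DMSO), 1 (total Med14), 1 (total Med17), 0 (total Med14 minus Med17 change) and 0 (total strains in DMSO). With a library left out in turn, the genes called numbered 19 to 64 higher (new Med14), 61 to 115 higher (new Med17), 106 to 244 lower (new Med14 minus Med17 change), 555 to 1569 lower and 201 to 380 higher (new strains in DMSO) and 53 to 109 higher (total Med14). Called genes numbered 41 to 112 lower and 1408 to 2247 higher (total Med14 minus Med17 change), 86 to 397 lower and 280 to 562 higher (total strains in DMSO), 0 to 5 higher (new minus total Med14) and 4 to 18 higher (new minus total Med17). Over all genes the median came to -1.92 to -1.79 (new Med14), -2.81 to -2.63 (new Med17), 0.75 to 0.90 (new Med14 minus Med17 change) and -1.43 to -1.31 (total Med17). Lists past the test numbered 3 to 9 (new Med14), 2 to 4 (new Med17) and 4 to 7 (total Med17). The replicate block changed no call of the 166 named results, and of 58 list results it ended 3, with adjusted p of 0.0588 (Yap1-type, difference in new RNA), 0.100 (ribosome biogenesis, total RNA, Med17) and 0.109 (proteasome, total RNA, Med17). All 166 named gene results kept their call without a filter on low counts and with a mean count of at least 50. Of these results 164 kept their call with DESeq2 and 2 lost it, and 102 of those fitted kept theirs with only the libraries of a strain. Of 58 list results 6 kept their call with an estimated correlation and 52 lost it.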

Other observations

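The GO terms of the deposited annotation were tested after the list results were seen, and gave groups not fixed beforehand. Genes of the ascospore wall, the coat of the yeast spore, fell less than other genes in newly synthesized RNA. In the Med14 strain 7 were lower and 1 higher of 11, median -1.29 (camera adjusted p = 0.00101, and 0.999 with an estimated correlation). In the Med17 strain 5 were lower and 1 higher of 11, median -1.12 (camera adjusted p = 0.00667, and 0.966 with an estimated correlation). The larger term ascospore wall assembly (42 genes) did not share this in the Med17 strain. Its medians were -1.75 (Med14) and -2.80 (Med17), against -1.86 and -2.71 for all genes (camera adjusted p = 0.0410 and 0.411). Genes for mitochondrial translation, which serve protein synthesis inside the mitochondrion, fell more with Med17, by the difference of Med14 minus Med17 change. In total RNA 0 were lower and 85 higher of 100, median 1.01 (camera adjusted p = 1.49e-08, and 0.974 with an estimated correlation). In newly synthesized RNA 1 was lower and 91 higher of 100, median 1.04 (camera adjusted p = 0.00300, and 0.976 with an estimated correlation). Over all genes these medians were 0.54 and 0.82, with 2322 of 5625 and 3619 of 6072 genes higher.

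Genes of selective autophagy also fell more with Med17 in newly synthesized RNA. Most genes did, with 3619 of 6072 called higher in this difference and an all-gene median of 0.82. For the Cvt pathway, which brings hydrolases to the vacuole, the difference had 0 lower and 48 higher of 50, median 1.31, camera adjusted p = 9.55e-05; adjusted p = 0.976 with an estimated correlation. The phagophore assembly site, where autophagosomes form, had 0 lower and 37 higher of 39, median 1.36, camera adjusted p = 0.000339; adjusted p = 0.976 with an estimated correlation, and late nucleophagy had 0 lower and 15 higher of 17, median 1.88, camera adjusted p = 0.00547; adjusted p = 0.976 with an estimated correlation. Ubiquitin-dependent catabolism by the proteasome had 0 lower and 47 higher of 52, median 1.21, camera adjusted p = 0.00243; adjusted p = 0.976 with an estimated correlation. The small-subunit processome, which assembles the small ribosomal subunit, lay below other genes with 1 lower and 7 higher of 52, median 0.078, camera adjusted p = 4.14e-06; adjusted p = 0.976 with an estimated correlation. Of 643 terms tested in newly synthesized RNA, 8 were called in the Med14 contrast, 1 in the Med17 contrast and 110 in the difference; of 635 in total RNA, 23, 44 and 87. With an estimated correlation none of these terms was called in any of the 6 contrasts (lowest adjusted p = 0.9445).

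SCR1 made up 0.498% of the counts of newly synthesized RNA in DMSO and 1.10% with auxin in the Med14 strain, and 0.364% and 1.95% in the Med17 strain. Genes of the mitochondrial genome made up 0.0439% and 0.212%, and 0.0273% and 0.205%. In the authors' deposited table, the pair of numbered groups closest to the Med14 contrast of newly synthesized RNA shared 5618 lower and 19 higher genes with the calls made here. Without ribosomal protein genes, the 1109 other genes of the highest expression class had median changes of -1.88 (Med14) and -2.44 (Med17) and a difference of 0.52.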
